A study of Mus musculus with 9 samples.

How the data were processed

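The data are 9 RNA sequencing libraries of mouse white gastrocnemius, 5 from Gaa knock-out mice at 5 months, 2 from wild-type mice at 5 months and 2 from wild-type mice at 6 months. Per the labels' protocols, RNA was extracted with Trizol, libraries were made from total RNA with the Illumina TruSeq kit, and the knock-out targets exon 6 of Gaa in a colony of mixed background bred by brother-sister matings for over 20 generations. The authors deposited 1 table of RPKM values (read counts scaled to transcript length and library size), 1 line per RefSeq transcript and 1 column per library, so replicates were not pooled. Per the submitters' processing notes, the genome build was mm9 and the tools were TopHat 1.3.2, Bowtie 0.12.7.0 and Partek 6.6. The role of each tool, the treatment of strand and any filter are not given in the sources used here.

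The table held 23665 transcripts. Their RPKM values were summed to 18063 genes, of which 3516 had several transcripts. Gene symbols that a spreadsheet had turned into dates were found on 39 lines, and 37 were restored through the transcript accession. The reference annotation at hand is of the assembly GRCm38, not mm9, so it was used only for names, transcript lengths and the order of genes on chromosomes, and no coordinates are given; 22782 transcripts matched it. Of the tested genes, 98.6% had a length and 98.9% a position. Every value column was used. The 5 knock-out columns match 1 sample each. The 4 wild-type columns show the genotype but not the age, so they were used as 1 arm, and the planned comparison of 6 with 5 months was not run. In its place, all 3 ways of pairing the 4 columns were fitted in models of 3 groups, an alternative chosen after the data were seen.

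Depth was estimated from the low values. Where whole reads are counted, RPKM times transcript length moves in steps of 1 read, and 1 RPKM of 1 kilobase stood for 17.7 to 37.7 reads in the knock-out and 37.3 to 64.7 in the wild type. Between 69.5% and 74.0% of values of at most 5 reads lay within 0.1 of a whole number, where chance gives 20%. This covers counting only. RPKM totals were 349239 to 374056 in the knock-out and 315337 to 327517 in the wild type, so they were higher in all knock-out libraries. The 20 most abundant genes took 42.6% to 45.5% of the total in the knock-out and 44.8% to 46.8% in the wild type. No pair of replicates matched within sampling noise: the chi-square per gene, for genes of 40 to 2000 estimated reads, was 2.41 to 9.83 between replicates, so no library was counted as a repeat of another.

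RPKM values are not counts, so no count model was used. Genes with a mean RPKM of at least 0.5 over the 9 libraries were tested on log2(RPKM + 0.1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided), 5 knock-out against 4 wild-type libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 0.1) scale, which understates the change of low genes. Gaa also had an exact permutation test over all 126 splits. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9. The step was tested on simulated data: of genes given a change of 0.5 on the log2 scale 55.9% were recovered among 11032 genes, of those with a change of 1 92.4% and of those with a change of 2 100%, and 6 unchanged genes were called. Only 68, 66 and 66 genes were given these changes, against 5713 called in the real data, so the rates may not carry over. Of 32 simulated lists, the 6 shifted by 0.5 were all found and no other was called. The simulated noise was independent between genes, so it could not show false calls of lists whose members move together. In the real libraries the estimated correlation between members ran from -0.03 for the vacuolar ATPase to 0.83 for endothelial markers.

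Before the data were examined, 34 gene lists were fixed for muscle pathways, fibre types, other cell types of muscle and sample handling. Of their 898 symbols, 894 were found in the table, 8 of them through an accession. Lists with at least 3 measured genes were tested with limma's camera (preset correlation 0.01) and Benjamini-Hochberg adjustment over the 32 lists tested. Each list's members were also counted by the threshold over all genes and adjusted over the list alone. Camera with an estimated correlation called 0 of the 32 lists (adjusted p from 0.28 to 1, with 3 lists at an unadjusted p below 0.05), fry called 19, and 10 were called with the preset one. A test added later, an exact permutation of the list mean less the mean of all genes, needs no assumed correlation between genes. Its smallest p is 0.0079, or 0.023 after adjustment over the lists. It asks only whether the list mean parts the genotypes more than other splits do. In these libraries that is common: 3410 of 11032 single genes lay all above and 1263 all below the wild-type values. The test called 11 of the 32 lists, so a call by it does not set a list apart from other genes.

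The genes named in the text follow a rule fixed beforehand: Gaa, then the 10 largest increases and 10 largest decreases among genes past the threshold with no overlap between the genotypes and a mean of at least 1 RPKM in the higher arm, then up to 4 members of each list with the smallest adjusted p where at least 3 members passed or the list was called. This names 138 genes. Where a few other genes are named, the text says so. Members of multigene families, such as haemoglobins, glutathione transferases, kallikreins, histones and Dynlt1 copies, and overlapping genes are uncertain, since the counting of shared reads and the use of strand are not given in the sources used here.

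The alternatives tried were pseudocounts of 1 and 0.01, no filter and a filter at 2 RPKM, quantile normalization, centring of each library on its median log ratio, a robust fit with array weights, a call that also needs a 2-fold change, the highest transcript in place of the sum, camera with an estimated correlation, fry, and leaving out each library in turn. Chosen after the data were seen were the removal of a lowess trend on transcript length, equal RPKM totals, leaving out wt1 and wt2 or wt3 and wt4, the wild-type pairs, the exact permutation of list means and the families of genes in the closing observations, which were taken by the start of the gene symbol, without pseudogenes and without genes that share a symbol start but belong elsewhere.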

Results

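RNA sequencing was used to measure transcript abundance in the white part of the gastrocnemius, a calf muscle, of mice that lack acid alpha-glucosidase and of wild-type mice. Acid alpha-glucosidase, the product of the Gaa gene, degrades glycogen inside lysosomes, and its loss causes Pompe disease, a glycogen storage disorder that affects muscle. The knock-out mouse is a model of this disease, and the comparison asks how gene expression in its muscle differs from that of wild-type mice. There were 5 libraries from knock-out mice at 5 months of age, 2 from wild-type mice at 5 months and 2 from wild-type mice at 6 months. All were described as of mixed background. The names of the 4 wild-type value columns (wt1 to wt4) carry no age, so both ages form 1 wild-type arm. The labels number the libraries without naming the mice, so p-values measure the spread between these libraries. Values were read counts scaled to transcript length and library size (RPKM), summed per gene. By the step of a single read in the low values, 1 RPKM of a transcript of 1 kilobase stood for an estimated 17.7 to 37.7 reads in the knock-out libraries and 37.3 to 64.7 reads in the wild-type libraries.

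Gaa itself was read first, as a check on the labels. Its summed RPKM lay between 3.11 and 3.64 in the knock-out libraries (3.44 ± 0.204, SD, n = 5) and between 46.0 and 56.0 in the wild-type libraries (49.4 ± 4.48, SD, n = 4). The knock-out mean was 6.97% of the wild-type mean. The log2 fold change was -3.80 (SE 0.07, limma adjusted p = 1.8e-11), and the exact two-sided permutation p was 0.0079, the smallest that the 126 splits of 9 libraries into 5 and 4 can give. The targeting disrupts exon 6, so reads from the remaining exons can persist. All 9 libraries had the Gaa level their genotype label calls for.

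**Figure D1:**
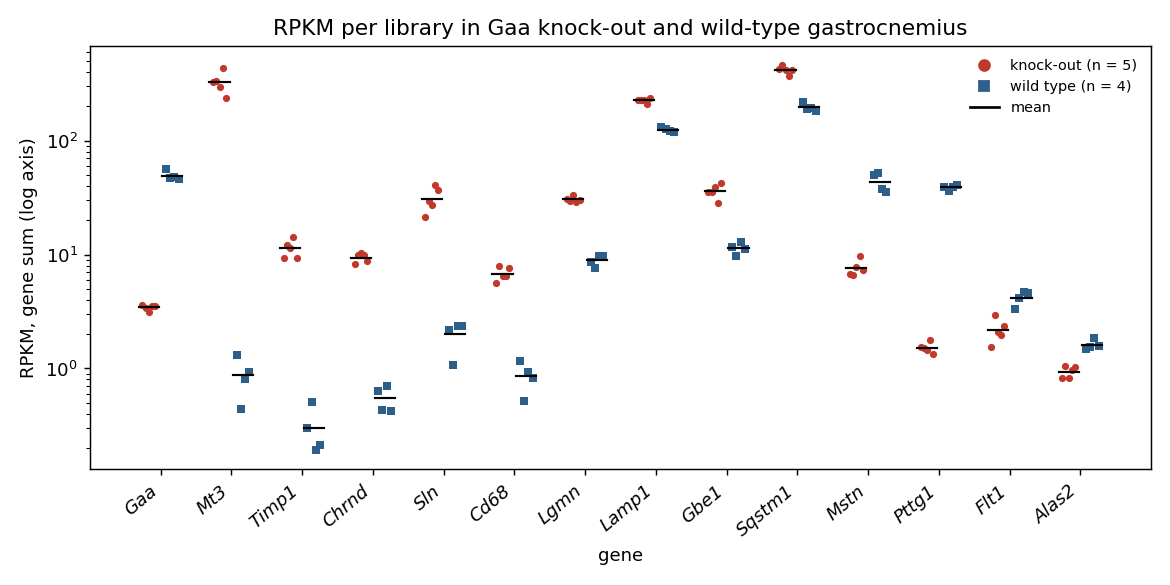
RPKM (log axis) of 14 genes named in the text, with each knock-out library as a circle (n = 5), each wild-type library as a square (n = 4) and the mean of each genotype as a bar. Gaa lies between 3.11 and 3.64 RPKM in the knock-out libraries and between 46.0 and 56.0 in the wild-type libraries, and the groups do not overlap for any of the genes drawn.

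Of 11032 genes tested, 5713 (51.8%) differed between knock-out and wild type, 4081 higher and 1632 lower in the knock-out (limma, Benjamini-Hochberg adjusted p below 0.05). A change of at least 2-fold was found for 686 genes, 529 higher and 157 lower. The 5 knock-out values all lay above the 4 wild-type values for 3410 genes and all below for 1263 genes, where chance gives 1.59% of genes in both directions together. The first principal component held 71.7% of the variance and parted the genotypes. The median gene was 0.12 higher in the knock-out on the log2 scale, and centring each library on its median left 5507 changed genes, 2765 higher and 2742 lower, of which 4397 were also called without centring. The shift went with transcript length: of the changed genes, 84.1% were higher among the 3625 genes with the shortest transcripts, 71.4% among the 3625 in the middle and 55.4% among the 3625 with the longest. Some directions turned with the scaling, such as Myoz1 from 0.39 to -0.02 with quantile normalization, and list medians named below are also given relative to the median gene. Library and sequencing batches are not given in the sources used here, so the counts may include a batch difference that follows genotype.

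Metallothioneins, small proteins that bind zinc and copper, were among the largest increases. Mt3 rose from 0.869 ± 0.353 to 327 ± 73.7 RPKM (log2 fold change 8.45, SE 0.24, adjusted p = 4.4e-10). Mt4 was listed at 0 in all 4 wild-type libraries and at 7.01 to 12.3 RPKM in the knock-out libraries. Mt2 rose from 26.8 to 357 RPKM (log2 fold change 4.40, SE 0.57, adjusted p = 6.0e-05), although its wild-type values were scattered at 27.5, 66.6, 6.12 and 7.01 RPKM. Also among the 10 largest increases were Timp1, an inhibitor of matrix metalloproteinases (29.2-fold), Kcnn4, a calcium-activated potassium channel (19.7-fold), Fetub (27.4-fold), Klk1 (33.9-fold), Gsta1, a glutathione transferase (25.7-fold), Dynlt1a, a dynein light chain (21.1-fold), and the uncharacterised AA465934 (50.0-fold). Klk1, Gsta1 and Dynlt1a belong to families of near-identical copies, so reads could have been assigned to the wrong member. Where the wild-type level is near 0 the size and the order of the folds rest on the pseudocount: between pseudocounts of 1 and 0.01 the log2 fold change ran from 2.30 to 7.31 for Klk1, from 2.08 to 6.36 for Gsta1, from 2.35 to 6.01 for Fetub and from 2.26 to 5.01 for Kcnn4, with Dynlt1a moving alike. Timp1 ran from 3.23 to 5.26, and AA465934 was at 4.26 with a pseudocount of 1.

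The 10 largest decreases included Gaa itself. Tmem232 fell 35.2-fold from 8.23 ± 1.26 RPKM (log2 fold change -5.14, SE 0.17, adjusted p = 1.5e-09), or from -3.01 to -5.85 on the log2 scale with pseudocounts of 1 and 0.01. Pttg1, the securin that inhibits separase, fell from 38.9 to 1.52 RPKM (24.1-fold, adjusted p = 1.6e-11). Pla2g7, which inactivates platelet-activating factor, fell from 50.3 to 3.68 RPKM (13.5-fold). The others were 2610507I01Rik (18.4-fold), 1700001O22Rik (12.8-fold), Fgfbp1, a carrier of fibroblast growth factors (12.1-fold), the potassium channel gene Kcnf1 (10.2-fold), Odf3l2 (10.2-fold) and Dkk3 (9.89-fold). With a pseudocount of 1 the log2 fold change was -2.19 for 2610507I01Rik, -2.90 for 1700001O22Rik, -2.18 for Fgfbp1, -1.75 for Kcnf1 and -1.89 for Dkk3. For Kcnf1, Odf3l2 and Dkk3 the wild-type libraries differed among themselves: Dkk3 was at 6.22, 6.94, 1.97 and 2.01 RPKM in wt1 to wt4.

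Genes of the lysosome, the compartment in which Gaa acts, were higher in the knock-out, together with macrophage markers. Of 56 lysosomal enzymes and membrane proteins measured, 38 rose, 2 fell (Npc1 and Laptm4b, named after their values were seen) and 16 did not pass the test. Adjusted over the list alone the counts were 40 and 3, and with centring 33 and 7. Legumain (Lgmn), a lysosomal protease, rose from 8.95 ± 1.00 to 30.6 ± 1.66 RPKM, Hexa, a subunit of beta-hexosaminidase, from 14.1 ± 0.989 to 36.7 ± 2.30, Cd63 from 39.5 to 104 and the abundant membrane protein Lamp1 from 125 ± 5.70 to 226 ± 9.62. The list median was 0.47, or 0.35 above the median gene, and the list was called higher (camera adjusted p = 5.4e-04), but not with an estimated correlation between genes (adjusted p = 0.69 with an estimated correlation). By the exact permutation test of the list mean it was called higher (adjusted p = 0.023). The mean difference of the list was 0.43 (SE 0.06), and 0.25 (SE 0.14) at equal macrophage mean. The latter is an extrapolation, since the macrophage means of the genotypes did not overlap. Of 18 subunits of the vacuolar ATPase, the proton pump that acidifies lysosomes, 14 rose and none fell (14 and 1 adjusted over the list alone). Atp6v1e1 rose from 46.3 ± 1.19 to 71.8 ± 1.75 RPKM and Atp6v1a from 4.79 to 8.24. This list was called higher (adjusted p = 0.0058, and adjusted p = 0.28 with an estimated correlation), and the call ended when a trend with transcript length was removed from each library (adjusted p = 0.07, the highest of the camera settings, which began at 5.9e-05). On the values as deposited, the exact permutation test called the list higher (adjusted p = 0.023).

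The autophagy machinery, which delivers cargo to lysosomes, had 22 of 45 measured members higher and 6 lower (22 and 6 adjusted over the list alone, but 15 and 13 with centring), and was not called as a list (adjusted p = 0.59). The members with the smallest p-values were the cargo and membrane tags: Map1lc3a rose from 74.0 ± 7.88 to 191 ± 13.2 RPKM, Sqstm1 (p62, an autophagy receptor) from 198 ± 16.1 to 421 ± 31.6 and Gabarap from 53.5 to 88.0. Ulk1, the kinase that starts autophagy, fell from 14.5 ± 0.574 to 9.20 ± 0.567 RPKM. Genes of glycogen metabolism, the substrate that accumulates in Pompe disease, went both ways: 6 of 27 rose and 7 fell, the same counts adjusted over the list alone (6 and 10 with centring), and the list was not called (adjusted p = 0.24). Gbe1, the glycogen branching enzyme, rose from 11.3 ± 1.24 to 36.2 ± 5.35 RPKM. The glucose transporter Slc2a1 rose from 1.73 to 5.67 RPKM and the hexokinase gene Hk1 rose 3.14-fold. Phkb, a subunit of phosphorylase kinase, fell from 138 ± 9.09 to 93.0 ± 5.07 RPKM. The list median was -0.04 (-0.16 relative to the median gene) and its mean 0.17, so the 2 differ in sign, and the test pointed down.

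**Figure D2:**
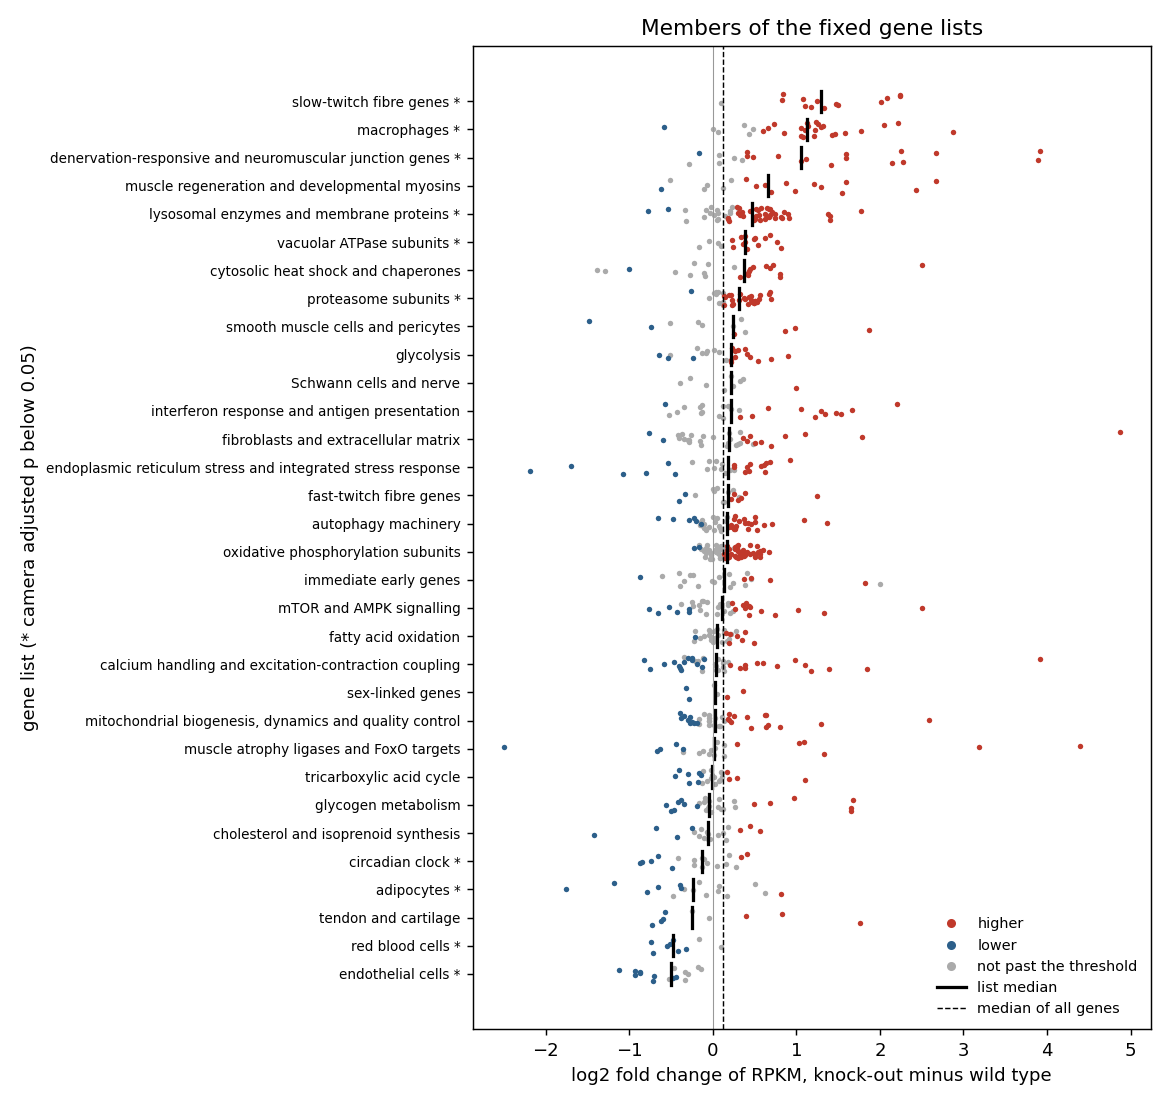
Log2 fold change of RPKM (knock-out minus wild type, horizontal axis) of each measured member of the 32 gene lists tested, 1 point per gene, coloured by whether the gene passed the adjusted threshold, with the list median as a thick bar and the median of all genes (0.12) as a dashed line. Lists marked with an asterisk were called by camera: macrophages have a median of 1.13, lysosomal enzymes and membrane proteins of 0.47 and endothelial cells of -0.50.

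Markers of other cell types moved in both directions. Of 29 macrophage markers measured, 23 rose and 1 fell (24 and 1 adjusted over the list alone), with a median of 1.13 (1.01 relative to the median gene), and the list was called higher (camera adjusted p = 1.8e-04, and adjusted p = 0.69 with an estimated correlation). By the exact permutation test of the list mean it was also called higher (adjusted p = 0.023). Cd68, a lysosomal glycoprotein of macrophages, rose from 0.865 ± 0.268 to 6.82 ± 0.969 RPKM, Ctss, a protease, from 1.82 to 6.38, Mpeg1 from 0.382 to 1.92 and the lipid receptor Trem2 from 0.194 to 1.26. The member that fell was Lyve1, named after its value was seen, a marker of resident macrophages and lymphatic vessels, from 2.07 to 1.37 RPKM. In the list of interferon response and antigen presentation 11 of 25 genes rose and 1 fell, the same counts adjusted over the list alone, and 9 and 5 with centring. The class II molecules H2-Aa, H2-Ab1 and H2-Eb1 rose 2.91-fold, 2.53-fold and 2.79-fold. The list was not called (adjusted p = 0.44), while an exact permutation test of the list mean, added after the data were seen, called it higher (adjusted p = 0.023). The difference rests largely on wt1 and wt2: the list mean was 1.35 in both, 1.85 and 1.84 in wt3 and wt4 and 1.95 to 2.18 in the knock-out, and camera gave 0.026 without wt3 and wt4 and 0.93 without wt1 and wt2, in a range of 0.026 to 0.98. Lymphocyte markers were too low to test as a list, with 2 genes measured, of which Cd3e, named after its value was seen, rose 3.92-fold to 1.31 RPKM from 0.0373, 0.0551, 0.711 and 0.832 in wt1 to wt4, and none of the neutrophil markers reached the expression filter.

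Endothelial markers were called lower in the knock-out, with overlap between the genotypes. Of 16 measured, 9 fell and none rose (11 and 0 adjusted over the list alone), with a median of -0.50, which is -0.62 relative to the median gene (camera adjusted p = 7.3e-05, and adjusted p = 0.69 with an estimated correlation). Sox18 fell from 2.98 ± 0.591 to 1.33 ± 0.310 RPKM, the receptor of vascular endothelial growth factor Flt1 from 4.18 to 2.18, Ptprb from 4.81 to 2.58 and Esam from 8.26 to 5.11. The list mean of ko2 (2.06 on the log2 scale) lay above those of wt1 (1.75) and wt2 (2.01), with the other knock-out libraries at 1.28 to 1.51. The endothelial mean less that of all genes was not past the threshold by the exact permutation test (adjusted p = 0.054). Red blood cell genes also fell, 7 of 9 measured with none higher (7 and 0 adjusted over the list alone, camera adjusted p = 8.5e-04, and adjusted p = 0.4 with an estimated correlation): Alas2, the first enzyme of haem synthesis in red cells, from 1.61 ± 0.171 to 0.939 ± 0.110 RPKM, and the haemoglobin genes Hba-a1 from 98.4 to 68.4 and Hbb-b1 from 29.4 to 17.9, whose copies share reads. Adipocyte markers fell in 6 of 17 cases and rose in 1, the same counts adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.69 with an estimated correlation). Lep fell from 4.31 to 1.16 RPKM and Scd1 from 56.8 to 24.9. This call ended with the libraries centred (adjusted p = 0.056), without wt3 (0.074) and by the exact permutation test (0.054), and adjusted p ran from 7.5e-04 to 0.17 over the camera settings.

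The remaining cell type lists were not called. Fibroblast and matrix genes had 10 of 33 members higher and 2 lower (9 and 1 adjusted over the list alone, 9 and 7 with centring, adjusted p = 1). Besides Timp1, the proteoglycan gene Lum rose from 8.57 ± 2.12 to 28.9 ± 3.07 RPKM and the growth factor gene Tgfb1 rose 2.14-fold. Smooth muscle and pericyte genes had 4 of 12 higher and 2 lower (2 and 3 with centring, adjusted p = 0.84), with the pericyte genes Cspg4 at 2.49 RPKM against 0.622 and Rgs5 at 12.8 against 36.1, both past the threshold. Schwann cell genes had 1 of 9 higher (adjusted p = 0.92), and tendon and cartilage genes 3 of 9 higher, among them Cilp (3.39-fold), and 4 lower, among them Thbs4 (adjusted p = 0.57, with a median of -0.25, -0.37 relative to the median gene, and a mean of 0.02).

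Genes that respond to loss of innervation, together with those of the neuromuscular junction, showed large increases. Of 21 measured, 15 rose and 1 fell (Prrx1, by 1.12-fold, named after its value was seen; 17 and 1 adjusted over the list alone), with a median of 1.06 (0.94 relative to the median gene). Subunits of the muscle acetylcholine receptor rose: Chrnd from 0.551 ± 0.142 to 9.41 ± 0.861 RPKM (log2 fold change 3.89, SE 0.13, adjusted p = 1.6e-09) and Chrna1 from 2.09 ± 0.245 to 10.5 ± 1.11. With a pseudocount of 1 the log2 fold change of Chrnd was 2.75. The adhesion molecule Ncam1 rose from 0.847 ± 0.107 to 5.90 ± 0.375 RPKM. Sln, an inhibitor of the calcium pump of the sarcoplasmic reticulum, rose 15.2-fold to 31.1 ± 7.60 RPKM. The list was called higher (camera adjusted p = 2.2e-04, adjusted p = 0.28 with an estimated correlation and 0.023 by the exact permutation test). In the list of muscle regeneration and developmental myosins 12 of 18 genes rose and 1 fell (12 and 2 adjusted over the list alone), with the list itself at adjusted p = 0.052 and, by the exact permutation test, at 0.023. It was called higher with centring (0.011) and with the length trend removed (0.011), and adjusted p ran from 0.0064 to 0.094 over 30 other camera settings, 10 of which left it uncalled. Myogenin (Myog) rose from 0.773 to 2.44 RPKM, the imprinted RNA H19 from 65.1 ± 21.5 to 339 ± 36.7 and desmin (Des) from 1205 ± 161 to 2369 ± 133. The embryonic myosin Myh3, singled out after its value was seen, was at 1.01 RPKM in the knock-out and 1.04 in the wild type (adjusted p = 0.81).

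Slow-twitch fibre genes were higher, 13 of 14 with none lower (13 and 0 adjusted over the list alone, camera adjusted p = 0.036, and adjusted p = 1 with an estimated correlation). Tnnt1, the slow skeletal troponin T, rose from 14.2 ± 9.39 to 57.3 ± 19.5 RPKM, Fhl1 from 177 ± 62.5 to 479 ± 69.9, Atp2a2, the slow calcium pump, from 14.4 to 31.3 and Myoz2 from 16.2 to 33.9. Libraries within a genotype varied: the list mean of ko1 (5.08 on the log2 scale) lay below that of wt1 (5.22). The call was lost without ko2 (adjusted p = 0.054), ko5 (0.052), wt2 (0.06) or wt4 (0.062) and by the exact permutation test (0.068), and adjusted p ran from 3.1e-04 to 0.24 over the camera settings. Fast-twitch genes had 6 of 17 higher and 2 lower (2 and 3 with centring, adjusted p = 0.91): Myh2, the fast oxidative myosin, rose from 158 to 364 RPKM, and Casq1 and Myl1 fell from 1314 to 986 and from 7283 to 5781 RPKM.

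Of 38 proteasome subunits, 28 rose and 1 fell (28 and 1 adjusted over the list alone), by small amounts: Psmc5 from 58.7 ± 0.646 to 85.8 ± 3.56 RPKM and Psmb1 from 43.7 ± 1.15 to 61.3 ± 0.581. The list was called higher (camera adjusted p = 6.8e-04, adjusted p = 0.36 with an estimated correlation and 0.023 by the exact permutation test), with a median 0.19 above the median gene. With the length trend removed the counts were 16 higher and 6 lower and the camera call ended (adjusted p = 0.13, the highest of the camera settings, which began at 1.7e-06). Atrophy ligases and FoxO targets went both ways, 6 of 21 higher and 5 lower (5 and 7 with centring), with a median of 0.01, or -0.11 relative to the median gene, and the test pointing down (adjusted p = 0.44). The list mean depends on the wild-type libraries: it was 3.97 and 4.10 in wt1 and wt2, 3.64 and 3.57 in wt3 and wt4, and 4.05 to 4.16 in the knock-out. Adjusted p ran from 0.17 to 0.93 over the other camera settings. The ubiquitin ligase Trim63 (MuRF1) rose from 93.0 ± 25.9 to 193 ± 16.9 RPKM and Eif4ebp1, a repressor of translation, from 23.5 to 59.3. Trim63 was at 112 RPKM in wt1 and wt2 and 73.5 in wt3 and wt4 (limma adjusted p = 0.03). Myostatin (Mstn), a negative regulator of muscle mass, fell from 43.8 ± 8.43 to 7.62 ± 1.22 RPKM (log2 fold change -2.50, SE 0.13, adjusted p = 6.1e-08).

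Calcium handling and excitation-contraction coupling was divided, with 13 of 42 genes higher and 14 lower (13 and 15 adjusted over the list alone, 12 and 18 with centring, adjusted p = 0.32). Its median of 0.04 lay below the median gene (-0.08 relative to it) and its mean of 0.19 above. The calcium channel subunits Cacng1 and Cacnb1 rose from 145 ± 15.1 to 524 ± 77.7 RPKM and from 46.7 ± 3.96 to 122 ± 8.94, and S100a1 rose from 83.4 to 165. Among cytosolic chaperones 12 of 22 rose and 1 fell (adjusted p = 0.59), led by the small heat shock protein Hspb7, from 35.4 ± 18.1 to 188 ± 34.3 RPKM. The member that fell was Hspa1l, a testis-type Hsp70, from 6.31 to 3.10 RPKM. The knock-out list means (4.98 to 5.19 on the log2 scale) lay between wt3 and wt4 (4.52 and 4.45) and wt1 (5.39), with wt2 at 5.14, and without wt1 and wt2 the list was called higher (adjusted p = 0.0015, in a range of 0.0015 to 0.94). In the list of endoplasmic reticulum stress and the integrated stress response 12 of 28 genes rose and 6 fell (9 and 7 with centring, adjusted p = 1). Those with the smallest p-values were Xbp1, a transcription factor of the unfolded protein response (1.90-fold higher), the chaperone gene Canx (1.53-fold) and Manf (1.49-fold). The list median was 0.18 (0.06 relative to the median gene) and its mean -0.00. Among those that fell, named after their values were seen, were Chac1 (4.56-fold), Mthfd2 (3.26-fold) and Asns (2.11-fold), which respond to amino acid shortage. The folds of Mthfd2 and Asns depend on the wild-type libraries: Mthfd2 was at 1.99 RPKM in wt1 and wt2 and 7.27 in wt3 and wt4 (adjusted p = 5.8e-04), against 1.11 in the knock-out, and Asns at 1.34 and 3.24 (adjusted p = 0.039), against 0.969.

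Of 78 subunits of oxidative phosphorylation, 42 rose and 2 fell (the same counts adjusted over the list alone, 24 and 10 with centring, list adjusted p = 0.063), with examples at Ndufa2 (1.59-fold) and Atp5g2 (1.42-fold). Their median was 0.05 above the median gene. With the length trend removed, 8 were higher and 29 lower, and the list was called lower (adjusted p = 0.029). It was called higher in 10 of the 30 other camera settings, among them no filter (0.0027) and without ko3 (0.023), ko5 (0.036) or wt3 (0.021), so its direction depends on how the short transcripts are treated. In the tricarboxylic acid cycle 4 of 24 genes rose and 7 fell (1 and 12 with centring, adjusted p = 0.12). Idh2 rose from 46.8 ± 8.35 to 99.9 ± 12.1 RPKM, while Pcx (1.37-fold) and Suclg2 (1.33-fold) fell. That list was called lower with centring (adjusted p = 0.018) and by the exact permutation test (adjusted p = 0.023), with a range of 4.0e-04 to 0.34 over the camera settings. Fatty acid oxidation had 7 of 30 genes higher and 1 lower (5 and 0 adjusted over the list alone, adjusted p = 0.82), but 1 higher and 4 lower with centring. Glycolysis had 12 of 23 higher and 3 lower (adjusted p = 1), but 5 and 7 with centring, with Gapdh at 247 ± 35.5 RPKM against 152 ± 16.2. In the list of mitochondrial biogenesis, dynamics and quality control 14 of 38 rose and 9 fell (adjusted p = 0.68), and the counts turned to 9 and 14 with centring. Park2, the ubiquitin ligase parkin, rose from 1.66 ± 0.0253 to 10.5 ± 0.835 RPKM (log2 fold change 2.59, SE 0.07, adjusted p = 3.9e-10), and Gpx1 from 27.4 to 67.8.

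Among genes of mTOR and AMPK signalling 14 of 36 rose and 6 fell (15 and 7 adjusted over the list alone, 11 and 12 with centring, adjusted p = 0.9). Prkag2, a regulatory subunit of AMPK, rose from 2.02 ± 0.363 to 11.8 ± 0.760 RPKM, while Prkab2, another subunit, fell from 99.5 ± 10.2 to 58.7 ± 3.98. Cholesterol and isoprenoid synthesis had 3 of 19 genes higher and 4 lower (1 and 6 with centring, adjusted p = 0.052, and 0.023 by the exact permutation test, lower). It was called lower in 9 of 30 other camera settings, among them without ko1 (0.038) or wt1 (0.016), in a range of 0.0086 to 0.3. Hsd17b7 fell from 2.50 to 0.878 RPKM, and Srebf2, which drives the pathway, rose from 2.31 to 3.18.

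The last lists were fixed as records of sample handling. Immediate early genes, which respond within minutes to stress and dissection, had 4 of 22 members higher and 1 lower (adjusted p = 0.59). That p covers opposite results: the list was called lower against wt1 and wt2 (1.9e-07) and higher against wt3 and wt4 (1.1e-04). Their wild-type values fell into a high and a low pair: Fos, named after its values were seen, was at 18.0, 9.88, 0.850 and 1.29 RPKM in wt1 to wt4, and between 3.17 and 4.82 in the knock-out. Circadian clock genes were called lower (adjusted p = 0.036, and adjusted p = 0.58 with an estimated correlation) with 5 of 18 lower and 2 higher (4 and 2 adjusted over the list alone, 9 and 2 with centring). The clock output gene Hlf fell from 3.56 to 1.94 RPKM and Rora 1.57-fold, while Tef rose from 62.2 to 82.7. The call ended with centring (adjusted p = 0.074) and without ko4 (0.064), wt1 (0.063) or wt2 (0.064), with a range of 0.0016 to 0.25 over the camera settings, while the exact permutation test called the list lower (0.023). Of 6 sex-linked genes, Eif2s3x and Kdm5d were higher and Kdm6a and Ddx3y lower (adjusted p = 0.68), by 1.13-fold to 1.28-fold, and Eif2s3x at 23.2 RPKM against 20.6 was not called with centring (adjusted p = 0.53), nor was Kdm5d (0.17). Kdm6a lost its call in 15 settings, Ddx3y in 11 and Kdm5d in 15, among them some that leave out a single library.

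Because the ages of the wild-type columns are not given, the 4 libraries were paired in each of the 3 possible ways. Pairing wt1 with wt2 and wt3 with wt4 gave 331 genes that differed between the pairs, 139 higher in the first pair and 192 lower (limma, adjusted p below 0.05). Of these, 17 immediate early genes, from a list fixed as a record of handling, were higher in wt1 and wt2 and 0 lower. For cytosolic chaperones the counts were 8 and 1. The other pairings gave 0 genes each, with 192 (1.74%) and 131 (1.19%) genes at an unadjusted p below 0.05, against 2049 (18.6%) in the first. Both low shares lie below what chance gives at that p. In those pairings the first difference falls within each pair and adds to the spread, so 0 calls do not show equal pairs. Which pairing, if any, follows age is open. Against any pair of wild-type libraries, the knock-out differed in 3983 to 5656 genes, and the log2 fold change of Gaa lay between -3.88 and -3.72.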

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

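The splits for the gene lists and the endothelial comparison are tests chosen after the results were seen. Of 348 groups of values tested by Dixon's ratio, 17 (4.89%) held a library far from the others of its genotype, and chance gives about 1 in 20 groups. In the knock-out, ko2 stood apart for Esam (7.41 RPKM, others 4.32 to 4.85), Kcnj8 (2.93, others 1.70 to 1.99), the endothelial list mean (2.06 on the log2 scale, others 1.28 to 1.51) and the cholesterol synthesis list mean (1.19, others 1.11 to 1.13). Library ko3 stood apart for Trem2 (0.777 RPKM, below the other 4), Hsd17b7 (1.27, others 0.753 to 0.795) and depth (17.7 estimated reads per kilobase at 1 RPKM, others 32.4 to 37.7), and ko4 for Cidec (8.39 RPKM, others 4.34 to 5.03). In the wild type, wt1 stood apart for Hspb7 (62.6 RPKM, others 25.2 to 27.1), Eci2 (34.5, others 27.1 to 27.6) and Myl1 (6777, others 7417 to 7505), wt2 for Sln (1.07, others 2.17 to 2.38) and wt3 for Ndufb3 (67.8, others 57.7 to 59.1). Library wt4 stood apart for Hbb-b1 (25.6 RPKM, others 30.2 to 31.0), Eif4ebp1 (19.7, others 24.4 to 25.1), the proteasome list mean (5.05 on the log2 scale, others 5.10 to 5.11) and the RPKM total (315337, others 326480 to 327517).

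Of 100 drawn splits of the 9 libraries into 5 and 4, the real one included, 1 called as many genes as the real split with its 5713, and the highest other called 3019. A chance split is thus unlikely to give this count of genes. A batch that follows genotype could give it too, and no batches are given. The 5 other splits that called any gene, 1611 to 3019, each put 1 knock-out library with all 4 wild-type libraries. For the count of gene lists called by camera chance is not excluded: 43 of the 100 splits called at least the 10 lists of the real split, and the highest other called 18. For the single lists, a camera p as small as the real one came in 1 of the 100 splits for denervation-responsive genes, 5 for lysosomal genes, 8 for the vacuolar ATPase, 12 for the proteasome, 21 for red blood cells, 24 for endothelial cells, 29 for macrophages, 31 for the circadian clock, 37 for adipocytes and 49 for slow-twitch genes. The exact permutation of list means, added after the data were seen, covered all 126 splits. There the real split gave the largest difference for denervation-responsive, lysosomal, vacuolar ATPase, proteasome, red blood cell, macrophage and circadian clock genes (adjusted p = 0.023). It did not for endothelial cells and adipocytes (0.054) or slow-twitch genes (0.068). Since 3410 single genes lay all above and 1263 all below the wild-type values, many sets of genes can reach the smallest p.

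Macrophage markers and lysosomal genes were higher together, and macrophages are rich in lysosomes, so macrophage RNA may bring part of the lysosomal transcripts. The lysosomal mean was 0.43 (SE 0.06) higher in the knock-out on the log2 scale, and 0.25 (SE 0.14, 6 residual degrees of freedom) at equal macrophage mean, with 0 genes shared by the lists. The lists are still not separate measures, since Cd68, in the macrophage list, is itself a lysosomal glycoprotein. The macrophage means did not overlap, at 0.98 to 1.75 in the knock-out and 0.05 to 0.40 in the wild type. The value of 0.25 is thus an extrapolation along the slope within genotypes, which was 0.17 (SE 0.12). With so uncertain a slope the adjustment cannot decide, and this explanation stays open. A lower share of fibre RNA as the only change would raise all other cell types alike. The endothelial median of -0.62 relative to all genes argues against this, although ko2 overlaps wt1 and wt2 there (exact adjusted p = 0.054). So does the red blood cell median of -0.59, with no overlap of list means between the genotypes once the mean of all genes is taken off (exact adjusted p = 0.023). A lower fibre share joined with a separate fall of these cells is not excluded. A response of the muscle fibres to the loss of Gaa stays open and was not tested.

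The genes with the largest changes could lie in chromosome segments that differ between the colonies, since the wild-type mice were not described as littermates. Around Gaa, the median absolute change of the 40 nearest measured genes was 0.24, at the 45.6 percentile of 10110 equal windows. This argues against a broad shift of the genes around Gaa. Of these neighbours 23 passed the threshold, 18 higher and 5 lower, where 51.8% of all tested genes did. A median stays in place when few neighbours differ, so it cannot exclude a carried segment that alters few genes. Elsewhere, 7 neighbouring pairs were found among the 140 genes changed at least 4-fold, against a 95th percentile of 4 in 10000 random orders (permutation p = 0.0019). Only 3 of the pairs (Perp with Tnfaip3, Dynlt1b with Tmem181b-ps and Dclk3 with Arpp21) reach outside the tandem Mt and Dynlt1 families, whose copies share reads or regulation, so strain segments and such families cannot be told apart here.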

How the results depend on the processing

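The wild-type pairs, the pairs left out, the length trend, equal totals and the exact permutation of list means were chosen after the data were seen. No paired analysis was possible because the wild-type columns carry neither replicate numbers nor ages. For the same reason the fits with age-matched wild type, with 6 months alone, with 3 groups by age and with a replicate block, and the comparison of wild-type ages, were not run. Gaa was lower in all 31 other settings (-3.96 to -3.50, and -3.83 to -3.74 without each library in turn). Without each library in turn, 5005 to 5554 genes changed, 3545 to 4083 higher and 1400 to 1597 lower, and 9 to 12 lists were called, 5 to 8 higher and 3 to 5 lower. The direction split moved with the scaling: 2644 higher and 3056 lower with quantile normalization, 2742 lower with centring, 2664 lower with the length trend removed, 2432 higher and 2814 lower with equal totals. A 2-fold limit left 686 genes, 529 higher and 157 lower, by its construction, and against wt1 and wt4 1075 were lower, the cause of which was not tested. No filter gave 6272 changed genes.

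Camera with an estimated correlation called 0 lists, 0 higher and 0 lower, with 3 at an unadjusted p below 0.05, and fry, which asks whether members differ from 0 and not from other genes, called 19, 16 of them higher. Directions turned with fry for mitochondrial biogenesis (8.6e-04), calcium handling (0.0021), endoplasmic reticulum stress (0.01) and mTOR and AMPK signalling (3.5e-04). They also turned for immediate early genes without wt1 and wt2 (1.9e-05) and against wt3 and wt4 (1.1e-04), and for oxidative phosphorylation with the length trend removed (0.029). The exact permutation called 11 lists. Of the 138 named genes, 122 kept their call and direction in every setting that gave them a value, the 2-fold limit aside (the filter at 2 RPKM gave 127 genes a value), 15 lost the call in at least 1 and 2 turned, Eif2s3x (-0.00) and Myoz1 (-0.02), with quantile normalization. Unless stated, the cause was not tested. Depth limits genes of low RPKM, most of all in ko3, the library with the fewest estimated reads.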

Other observations

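The gene families here, the length tests and the centring of changes of at least 2-fold were chosen after the data were seen. The p-values of the families therefore describe these data and are no independent support. Of 20 families, all 4 metallothioneins rose, a family picked because its members were among the largest increases, so its test adds nothing. Of 9 annexins, which bind membranes in the presence of calcium, 8 rose and 1 fell (camera adjusted p = 7.6e-04), with Anxa4 at 34.6 RPKM against 5.04, and of 8 S100 proteins 6 rose (0.0021). Of 81 cytosolic ribosomal proteins 73 rose and 2 fell (3.1e-11), and with the length trend removed 44 were higher and 4 lower (5.6e-05). The family tests used camera with the preset correlation of 0.01. They were not repeated with an estimated correlation, which called 0 of the 32 lists tested. Members of a family can move together, so the camera p-values of the families may be too small. Serpins (9 of 15 higher, 1 lower, 0.027), glutathione transferases (10 of 17 higher, 1 lower, 0.04) and keratins (3 of 4 higher, 0.039) were called higher, although the call of the glutathione transferases ended with the length trend removed (0.18). Of 14 histone genes 7 fell and none rose (2.2e-04). Zinc finger proteins were called lower as a group (0.04, and 0.18 with the length trend removed), with 52 of 266 higher and 42 lower as deposited, and 26 higher and 72 lower with centring. The other 11 families were not called by camera, while the exact permutation called 6 of them higher: tubulins, dual specificity phosphatases and chemokines (0.013), tripartite motif proteins (0.024), galectins and Rab GTPases (0.032).

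The excess of higher genes, 71.4% of the changed genes, may come from the scaling of RPKM. With each library centred the share was 50.2%, but centring sets the median change to 0, so that value decides nothing. Scaling stays open as a part of the cause for the changed genes as a whole. Among changes of at least 2-fold 65.2% were still higher with centring (63.7% to 67.2% without each library in turn), which argues against scaling as the whole cause there. The excess also went with length: the share of higher genes was 28.7 points greater among the shortest than among the longest transcripts, and the slopes on length ran from -0.10 to -0.01 in the knock-out and from 0.04 to 0.07 in the wild type (exact p = 0.0079, the smallest possible). With centring the gap was 35.2 points, 68.3% higher among the shortest and 33.1% among the longest. A single factor per library moves all genes alike, so these values argue against scaling as the only cause. Removing the trend left 50.7%, a step that also centres each library and so decides nothing either. A biological change in short transcripts, such as those of ribosomal proteins, stays open, as does a batch difference that follows genotype.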
